A study of Mus musculus with 46 samples.

How the data were processed

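Total RNA from individual testes of adult male Swiss mice was labelled with biotin and hybridised to Illumina mouse bead arrays with 25697 probes, 1 array per testis and 46 arrays in all. The mice had drunk water with no acrylamide or 5 concentrations of it from 0.001 to 10 µg/ml, each 10 times the one before, for 1, 6 or 12 months, per the labels. Arrays were grouped by dose and time as their titles give them, which made 18 groups.

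Both deposited tables were examined. The authors deposited non-normalized values, which are the summarised bead intensity of each probe on each array, on a linear scale, without detection p-values. The authors also deposited processed values, which are on the log2 scale. Per the labels these were made with lumi, whose version and settings are not given in the sources used here. Their columns share quartiles and extremes, and differences between dim probes are compressed. Set against log2 of the intensities of the same arrays, their median slope was 0.586 between log2 intensities of 7 and 8, 0.755 between 8 and 9, 0.891 between 9 and 10, 0.945 between 10 and 11 and 0.991 between 11 and 12. The log2 changes of dim probes are therefore understated.

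The plan made before the data were examined was to start from the non-normalized table and to use the processed values if that table proved unusable. Of its 45 columns used, 12 follow the order of the probe names, with a rank correlation with the processed values of at least 0.999954. The other 33 are in another order, with a rank correlation of at most 0.0122 in size, so their values stand beside the wrong probe names. The column named 1, which holds replicate 1 of the control at 1 month, was not used, because its name could not be told apart from a column number. The processed values were therefore used for every value reported. The order of the 33 columns was restored only for alternatives, by matching the ranks of each intensity value over the 33 arrays to those of the processed values. In this way 25692 probes were matched within 0.001 of the ranks and 5 were not.

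Genes were taken from the probe annotation that came with the table: 23978 probes had 1 symbol, 0 had several and 1719 had none. No genome build comes with these files, so chromosomes are given without positions. The dimmest 40% of probes by mean over all arrays, those under a mean log2 value of 7.76, were left out. The 15419 probes kept, of which 14502 had a symbol, were fitted together with limma (version 3.58.1, in R version 4.3.3), with a mean for each of the 18 groups and the spread pooled over all 46 arrays. Where a group had 1 array, that array was assumed to vary like the others. Contrasts were each dose against the control of the same time, a dose trend at each time (slope over the dose rank from 0 for the control to 5 for 10 µg/ml, in log2 per dose step), the mean of the 3 trends weighted by the inverse of their variance, the differences between the trends, and the differences between time points averaged over the 6 doses. P-values were adjusted over the probes tested by the method of Benjamini and Hochberg, with a threshold of 0.05.

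The gene lists were fixed before the data were examined. They cover 13 cell types or tissues: spermatogonia, spermatocytes, round spermatids, elongating spermatids, Sertoli cells, Leydig cells and steroidogenesis, peritubular myoid and smooth muscle cells, endothelial cells, macrophages and antigen presentation, lymphocytes and immunoglobulins, epididymis, adipose tissue and blood cells. The others cover acrylamide and xenobiotic metabolism, oxidative stress and NRF2 targets, p53 targets and DNA damage response, excision repair of damaged bases, meiotic recombination and synapsis, cholesterol synthesis, immediate early genes, interferon response, heat shock and unfolded protein response, and kinesins and dyneins. Each of the 23 lists was tested with camera from limma on 1 probe per gene, the brightest, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A value given for a gene as a member of a list is that of its brightest probe.

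The rule for the genes named was also fixed before the data were examined. In the comparisons of 10 µg/ml with control, the dose trends and the time comparisons it takes, among probes past the threshold with 1 symbol, the 12 with the largest rise and the 12 with the largest fall. Where fewer than 5 probes passed, it takes the 5 and 5 with the smallest p as values. In the other comparisons it takes 3 and 3. Up to 4 members of each list with the smallest p and Cyp2e1 are added in each comparison. Unnamed transcripts are skipped unless nothing else is left. Cyp2e1, whose 1 probe lies among those left out as dim, was tested in a fit of all probes and by a two-sided permutation test (100000 draws) of its slope over the dose rank at each time.

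The number of arrays limits the precision. On simulated data with the same groups and spread, 95.45% of probes shifted by 1 log2 were recovered for 10 µg/ml at 6 months and 37.31% of those shifted by 0.25, with 4 false calls among 137. At 12 months, with 1 array at 10 µg/ml, the shares were 77.27% and 14.93%. Neither shares nor false calls cover differences between sets of arrays.

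Alternatives planned before the data were examined were: no background correction, cyclic loess, no filter and a filter on the dimmest 60%, only the arrays of the times compared, the replicate number as a block, array weights, eBayes with an intensity trend and robust, 1 probe per gene, dose in µg/ml, the pooled trend without 12 months, time from controls only, an estimated correlation, other probes of each gene and each array left out in turn. Added after the data were seen were the restored intensities and blocks or comparisons by sets of 8 consecutive sample numbers, with and without 1 array that stands apart. Figures were drawn with matplotlib version 3.10.9.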

Results

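Acrylamide, a small reactive compound that forms when starchy food is heated, was given to male Swiss mice in their drinking water, and gene expression was measured in the testis on 1 array per mouse. Besides a control there were 5 concentrations, from 0.001 to 10 µg/ml, each 10 times the one before, and the mice were sampled after 1, 6 or 12 months, at 3 to 6, 11 to 12 or 16 to 17 months of age per the labels. Each group had 3 arrays, except 2 at 0.1 µg/ml and 1 month. At 12 months there were 2 control arrays, 2 at 0.001 µg/ml, 2 at 0.01 µg/ml, 3 at 0.1 µg/ml, 1 at 1 µg/ml and 1 at 10 µg/ml. The 25697 probes covered 16593 genes, and 15419 probes were bright enough to be tested. The median intensity before normalization ran from 108 to 222 over 45 arrays, and the number of arrays limited the precision. Values are log2 differences with the standard error of the limma fit, and a slope is the log2 change per step of the dose rank. All p-values of this fit are two-sided, and a count given as unadjusted is that of probes with an unadjusted p under 0.05.

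The labels number the arrays from 1 to 46 in the order of time and then dose. Arrays of this type hold 8 samples on a slide, but the labels give no slide, so a set here means 8 consecutive numbers, with 6 arrays in set 6. At 1 month the control and 0.001 µg/ml lay in set 1, 0.01 µg/ml in sets 1 and 2, 0.1 and 1 µg/ml in set 2 and 10 µg/ml in sets 2 and 3. At 6 months the control and 0.001 µg/ml lay in set 3, 0.01 µg/ml in sets 3 and 4, 0.1 and 1 µg/ml in set 4 and 10 µg/ml in set 5. At 12 months the control and 0.001 µg/ml lay in set 5, 0.01 µg/ml in sets 5 and 6 and the higher doses in set 6. The mean of the median intensities was 193, 148, 182, 117, 137 and 158 in sets 1 to 6. Neighbouring arrays of 1 group differed by a root mean square of 0.232 from set 1 to 2 and 0.293 from set 3 to 4. From set 2 to 3 and 5 to 6 it was 0.159 and 0.149. The mean was 0.208 across these borders (4 pairs) and 0.164 within a set (23 pairs; exact one-sided permutation p = 0.0166), leaving out 1 pair with an outlying array. With it the mean within a set was 0.191 (24 pairs; exact one-sided permutation p = 0.157). That array, replicate 3 of 0.001 µg/ml at 1 month, had a mean correlation of 0.844 with the other arrays over all 25697 probes, against at least 0.974 for every other array, and genes are not independent replicates. It was kept in the comparisons, and most probe counts that moved by more than 1.5 times without it are given.

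At 6 months, elongating spermatid genes fell as a list and single genes of Sertoli and smooth muscle cells rose in the testes of mice given 10 µg/ml (3 arrays) against control (3 arrays). Odf2, an outer dense fibre protein of the sperm tail (probe ILMN_1226849), was at 11.25 to 11.50 in the controls and 9.40 to 9.63 at 10 µg/ml, a fall of -1.90 ± 0.29 (adjusted p = 0.000241). Zpbp2, an acrosome protein that binds the zona pellucida, fell by 1.83 ± 0.37 (adjusted p = 0.00155), and Ropn1 of the fibrous sheath changed by -1.88 ± 0.46. Acta2, the smooth muscle actin, rose by 0.95 ± 0.17 (adjusted p = 0.000634), from 10.73 to 10.91 in the controls to 11.57 to 11.98. Serpinf1, a secreted protein also called pigment epithelium-derived factor, rose by 1.13 ± 0.23 (adjusted p = 0.002), and all 3 treated arrays lay above all 3 controls. Other large falls were those of Mff, the mitochondrial fission factor (-2.08 ± 0.61), Speer1 (-1.94), Fhl4 (-1.80), Bcl2l14 (-1.79), Cfap69 (-1.78), Morn2 (-1.74), Speer6-ps1 (-1.69), Cby2 (-1.69 ± 0.26) and Smc5 (-1.69). The largest rises were those of Lrrc18 (2.54 ± 0.79), Rps2 (1.10), Afap1 (0.97), Fads2 (0.96), Ugt1a10 (0.94), Fntb (0.94), Pld3 (0.91), Trpc4ap (0.89), Hspb6, a small heat shock protein of muscle (0.87 ± 0.14), and Retsat (0.85).

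Genes of late germ cells fell in this comparison. Of 21 elongating spermatid genes, 9 fell and 1 rose, with a median of -0.35 (camera adjusted p = 0.00205, adjusted p = 0.0312 with an estimated correlation). Over 11 alternatives the adjusted p ran from 2.2e-05 to 0.0674, and cyclic loess alone ended the call. The genes that fell included Tnp2, a transition protein of spermatid chromatin (-1.44), Spz1 (-1.40) and Akap4, the main scaffold of the fibrous sheath (-0.66 ± 0.09). Of 27 round spermatid genes, 8 fell and 3 rose, with a median of -0.22 (adjusted p = 0.0411, adjusted p = 0.199 with an estimated correlation), among them Crem, a transcription factor of spermatids (-0.89 ± 0.14), Spaca1 of the acrosome membrane (-0.74), Zpbp2 by its brightest probe (-1.45) and the kinase Tssk2 (-0.73). The call of the round spermatid list was lost without replicate 1 (adjusted p = 0.0524) or 3 (0.0797) of the control or replicate 2 of 10 µg/ml (0.0635). The lists of earlier germ cells did not pass. Of 21 spermatocyte genes, 4 fell, among them Tcte3 (-0.55) and Pgk2 (-0.35), and 2 rose, which were Ldhc, the testis lactate dehydrogenase (0.46), and Ybx2 (0.32; list adjusted p = 0.561). Of 17 spermatogonial genes, Dnmt3b rose (0.43) and Stra8 fell (-0.17; list adjusted p = 0.976). Of 18 genes of meiotic recombination and synapsis, 3 fell, with Syce2 at -1.02 and Sycp1 at -0.51, and Rad51c rose (0.30; list adjusted p = 0.18).

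Single somatic cell genes rose, and 0 somatic cell lists passed with camera. Of 26 Sertoli cell genes, 7 rose and 2 fell, with a median of 0.21 (list adjusted p = 0.087). Shbg, the androgen-binding protein, rose by 0.51 ± 0.07 (adjusted p = 0.00014), Dhh, the desert hedgehog signal, by 0.66, Aard by 0.53 and Fshr, the receptor of follicle-stimulating hormone, by 0.29. Of 8 myoid and smooth muscle genes 3 rose, with Mylk at 0.72 beside Acta2 (list adjusted p = 0.136). Among 26 Leydig cell and steroidogenic genes, Timp2 rose (0.77) and Hsd3b2 fell (-1.38; list adjusted p = 0.976), and of 18 genes of cholesterol synthesis 4 rose, which were Fdps (0.47), Insig1 (0.44), Nsdhl (0.37) and Lss (0.24; list adjusted p = 0.342). Robo4 rose (0.25) among 13 endothelial genes (list adjusted p = 0.302). With limma, 0 members passed among 18 macrophage, 6 lymphocyte, 11 epididymal, 9 adipose and 6 blood cell genes (list adjusted p = 0.976, 0.18, 0.392, 0.976 and 0.976).

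Stress and repair lists held changes in both directions. Of 29 genes of oxidative stress and NRF2 targets, 6 rose and 4 fell (list adjusted p = 0.976), with Gpx4, the selenoperoxidase of the sperm midpiece, at -0.82 ± 0.14, Me1 at -0.89, Prdx2 at 0.58 and Sqstm1, an autophagy receptor, at 0.55. Of 25 genes of acrylamide and xenobiotic metabolism, 3 rose and 2 fell (list adjusted p = 0.976), with Gstk1 at 0.65, Gstm2 at 0.53, Gstm5 at -0.68 and Gsta2 at -0.49. Of 32 excision repair genes, 3 rose and 4 fell (list adjusted p = 0.976), with Polb, the gap-filling polymerase, at -1.04 ± 0.15 (adjusted p = 0.000199), Aptx at -0.97, Poll at -0.44 and Parp1 at 0.51. Cdkn1a, the cell cycle inhibitor p21, rose by 0.34 among 25 p53 targets, of which 2 rose and 1 fell (list adjusted p = 0.976). Of 27 heat shock genes 4 fell, which were Hsf2 (-0.82), Hsp90aa1 (-0.72), Hspa4l (-0.60) and Hspe1 (-0.35; list adjusted p = 0.0911). Klf4 fell by 0.91 among 16 immediate early genes, of which 2 rose (list adjusted p = 0.976). Isg20 fell by 0.72 among 17 interferon genes (list adjusted p = 0.18). Of 32 kinesins and dyneins 3 rose and 3 fell (list adjusted p = 0.976), with Kif27 at -0.61 and Dnali1 at 0.46. Adjusted over the list alone, 2 elongating spermatid genes rose and 9 fell, 3 round spermatid genes rose and 9 fell, and 2 spermatocyte genes rose and 5 fell. Counted in the same way, 11 Sertoli cell genes rose and 2 fell, 4 myoid genes rose, 6 excision repair genes rose and 6 fell, 0 endothelial and 0 interferon genes passed with limma, and the other lists kept their counts.

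In all, 1388 probes rose and 1291 fell at 10 µg/ml and 6 months with limma (4841 unadjusted), with a median size of 0.413. By gene, 1232 had a probe that rose and 1136 a probe that fell, and 49 had both. Other probes of Odf2 were at -0.43, 0.19 and 0.36 (adjusted p = 0.00573, 0.652 and 0.0644), another probe of Mff rose (0.36, adjusted p = 0.00367) and another probe of Trpc4ap fell (-0.60, adjusted p = 0.0033). The count was 5073 without the array that stands apart, 1249 without replicate 1 and 1740 without replicate 3 of the control, and 1242 without replicate 3 of 10 µg/ml. Of the 24 genes with the largest changes, 10 lost their call without at least 1 array. All 3 arrays of 10 µg/ml lay in set 5 and all 3 controls in set 3, so no value within a set and no fit with the set as a fixed term could be had, and dose and set cannot be told apart here. With the set as a random term and without the array that stands apart, 2223 probes were called, and that fit cannot part dose from set either.

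**Figure D1:**
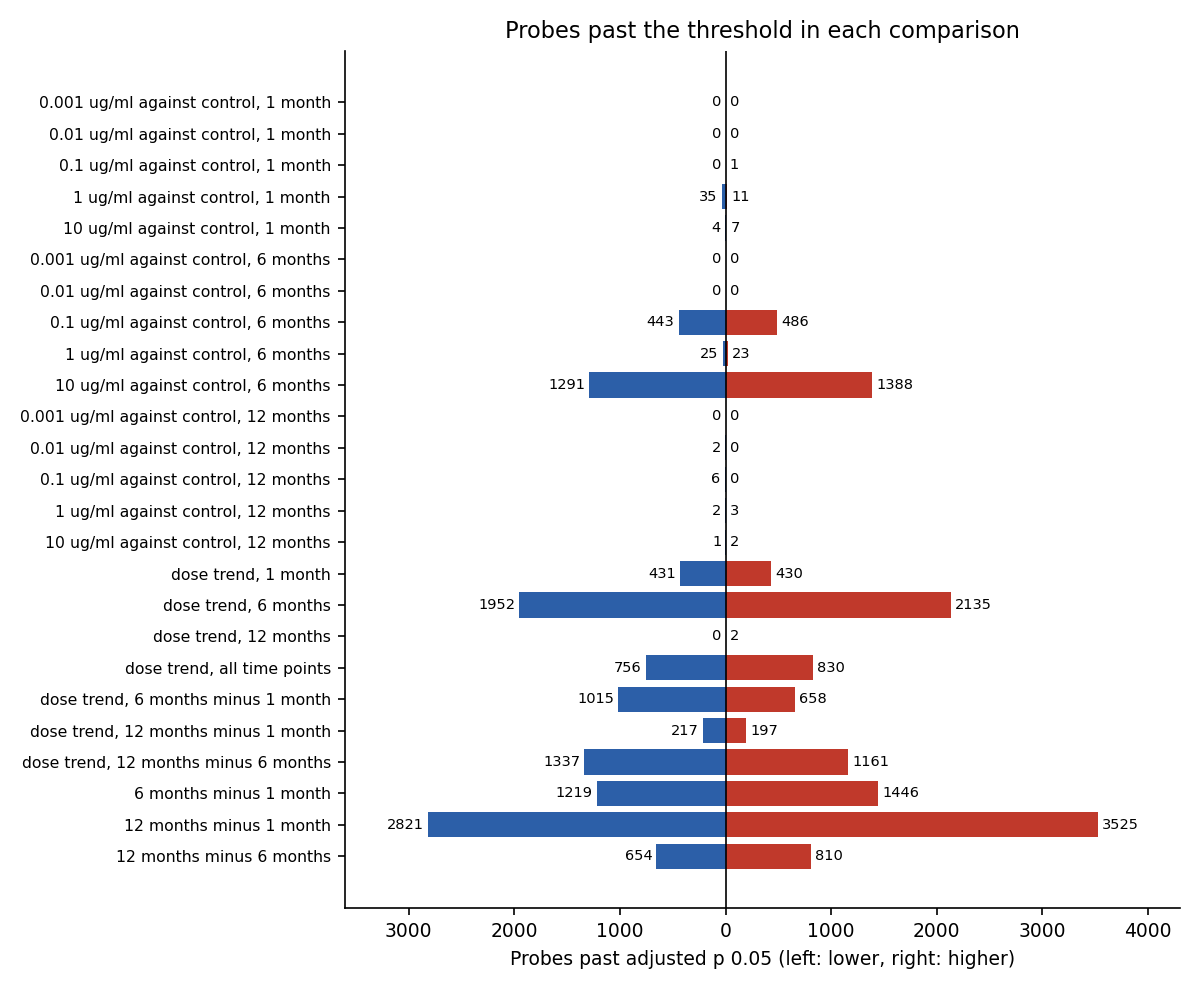
Number of probes past an adjusted p of 0.05 in each comparison, with probes that fell to the left of 0 and probes that rose to the right. At 6 months 1388 probes rose and 1291 fell at 10 µg/ml, and at 12 months 2 rose and 1 fell.

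The lower doses at 6 months, each with 3 arrays against the 3 controls, asked whether expression also differs below 10 µg/ml. At 0.1 µg/ml, 486 probes rose and 443 fell (3380 unadjusted), among them Lrrc18 (2.59 ± 0.79), Kcnab2 (1.15) and Serpinf1 (1.02 ± 0.23, adjusted p = 0.0139), with falls of Ms4a5 (-2.46 ± 0.65), Zpbp2 (-1.66 ± 0.37, adjusted p = 0.0115) and Ropn1 (-1.52). At 1 µg/ml, 23 rose and 25 fell (2567 unadjusted), with Zfpm1 (0.59 ± 0.13), Prox1, a homeobox factor (0.58), and Fam114a2 (0.57) higher and Odf2 (-1.34 ± 0.29, adjusted p = 0.0388), Pacrgl (-1.27 ± 0.21) and the steroid dehydrogenase Hsd3b2 (-1.16) lower. At 0.001 µg/ml, limma called 0 probes (140 unadjusted). The genes with the smallest p there were Fam20b (0.42, adjusted p = 0.102), Sh3d21 (0.25), Agbl5 (0.20), Lancl1 (-0.70), Gpr19 (-0.34) and Synm (-0.21). A fit with the set as a fixed term called 1 probe there, that of Fam20b at the same 0.42 (adjusted p = 0.00231). At 0.01 µg/ml limma also called 0 (1316 unadjusted), with Acaa2 at 0.60 (adjusted p = 0.155), Sqstm1 at 0.50, Copz2 at 0.62, Ruvbl1 at -0.41, Pdhb at -0.59 and Apoh at -0.91.

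Inside the 0.01 µg/ml group at 6 months, replicate 1 lay in set 3 and the others in set 4. The difference between them repeated that of 0.1 µg/ml against control over its 929 probes, with a slope of 0.961 and 97.74% of the signs (r = 0.916 across genes, which are not independent replicates). Within set 4, which held 8 arrays of 0.01, 0.1 and 1 µg/ml, the dose slopes of Zpbp2 (0.11), Ropn1 (0.08) and Odf2 (0.03) were above 0 and that of Serpinf1 was -0.22. Limma called 0 probes for that trend (626 unadjusted). A fixed term for the set rests here on the same step between replicate 1 and the other arrays of 0.01 µg/ml, so it is not separate evidence. With the set as a fixed term, 0 probes were called at 0.1 µg/ml (284 unadjusted) and 0 at 1 µg/ml (302 unadjusted). There Zpbp2 and Ropn1 at 0.1 µg/ml stood at 0.51 ± 0.36 and 0.47 ± 0.73, and Odf2 at 1 µg/ml at 0.38 ± 0.29, the opposite direction to that without the term. Lrrc18 (3.33 ± 1.40) and Kcnab2 (1.28 ± 0.56) at 0.1 µg/ml kept their size with wider errors, and Serpinf1 (0.17) and Ms4a5 (-0.56) shrank. At 1 µg/ml Fam114a2 was at 0.38, Prox1 at 0.25, Pacrgl at -0.10, Zfpm1 at 0.05 and Hsd3b2 at -0.04. When the set was a random term and the array that stands apart was left out, limma called 0 at 0.1 µg/ml (2419 unadjusted) and 0 at 1 µg/ml (1463). The 929 probes became 2852 without the array that stands apart, and 260, 402 and 192 without replicates 1, 2 and 3 of the control. They became 273, 206 and 377 without those of 0.1 µg/ml and 1408 without replicate 1 of 0.01 µg/ml. The 48 probes at 1 µg/ml became 1361 without the array that stands apart, and 3, 2 and 0 without replicates 1, 2 and 3 of the control. They became 6, 4 and 1 without those of 1 µg/ml, 600 and 152 without replicates 1 and 3 of 0.01 µg/ml at 6 months and 85 without replicate 3 of 0.01 µg/ml at 1 month. At 0.01 µg/ml, 858 probes were called without its replicate 1 and 8 without the array that stands apart. The 6 named genes at 0.1 µg/ml and the 6 at 1 µg/ml each lost their call without at least 1 array.

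**Figure D2:**
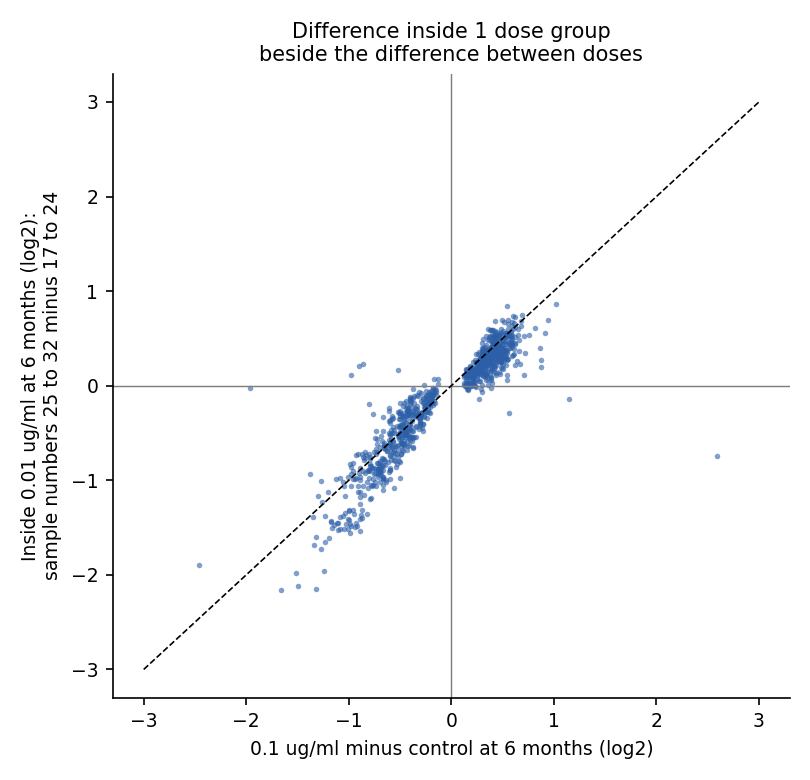
Each of 929 probes past the threshold for 0.1 µg/ml at 6 months, with its log2 difference from control on the horizontal axis and the log2 difference between sets 4 and 3 inside the 0.01 µg/ml group on the vertical axis. The dashed line marks equal values, and the slope over all 929 probes was 0.961.

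At 1 month a few genes differed between 10 µg/ml and control, with 3 arrays each. Got1l1, an aminotransferase-like gene, rose by 0.89 ± 0.18, Mrpl1, a mitochondrial ribosomal protein, by 0.65 ± 0.13, Ubb-ps by 0.56 ± 0.11, Akip1 by 0.51, the sperm lysozyme-like gene Lyzl1 by 0.48 and Tex43 by 0.40. Mrps21, another mitochondrial ribosomal protein, changed by -0.44 ± 0.09 and Ruvbl1, a chromatin helicase, by -0.38 ± 0.08, with 2 other Ruvbl1 probes at 0.08 and 0.13. Each of these had an adjusted p of 0.0476. In all 7 probes rose and 4 fell (1126 unadjusted), and 0 of the 23 lists passed. The count ran from 0 to 142 as each of the 46 arrays was left out, moved by more than 1.5 times by 40 of them, and was highest without the array that stands apart. These 8 genes and the unnamed transcript 1700001F09Rik (0.74), 9 in all, each lost the call without at least 1 array. Limma called 0 probes with the set as a fixed term (840 unadjusted). Under it Got1l1 (0.90 ± 0.36), Mrpl1 (0.78 ± 0.21) and Akip1 (0.82 ± 0.16) kept their size or grew with wider errors. Mrps21 was at -0.29, Ruvbl1 at -0.29, Ubb-ps at 0.18, Tex43 at 0.18 and Lyzl1 at 0.17. With that term and without the array that stands apart it called 98, among them Akip1 (adjusted p = 0.00984) and Mrpl1 (adjusted p = 0.038). The term brought 2 lists past the threshold, round spermatids (median 0.14) and heat shock genes (0.05), both higher (adjusted p = 0.047 each, 0.606 with an estimated correlation).

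Single genes passed at 2 of the lower doses at 1 month. At 1 µg/ml (3 arrays) 11 probes rose and 35 fell (1655 unadjusted). Abhd16a was at 3.28 ± 0.70 (adjusted p = 0.0373), Ubb-ps rose by 0.63, and Ldhc, the lactate dehydrogenase of germ cells, by 0.58 (adjusted p = 0.0133), while Nop9 (-1.21 ± 0.24), Spata21 (-1.16) and Mea1 (-1.14 ± 0.21, adjusted p = 0.0133) fell. At 0.1 µg/ml (2 arrays) Ubb-ps alone passed (0.73 ± 0.13, adjusted p = 0.0446; 912 unadjusted), with Ldhc at 0.58, Lrtm1 at 0.43, Akap1 at -1.08, Trpc4ap at -0.70 and Cxcr4 at -0.30. At 0.01 µg/ml (3 arrays) limma called 0 (308 unadjusted), with Abhd16a at 3.04 (adjusted p = 0.911), Ldhc at 0.43 (0.101), Ubb-ps at 0.47, Odf3b at -0.54, Pard6a at -0.40 and Neu1 at -0.34. In the fit with the set as a fixed term 4 probes rose there, those of Ldhc (0.47, adjusted p = 0.0407), Hook1 (0.70), Ibsp (2.08) and an unnamed transcript. Hook1 and Ibsp are named here after their values were seen, and 16 probes were called without the array that stands apart. At 0.001 µg/ml (3 arrays) it also called 0 (3967 unadjusted), with Ctdnep1 at 0.44, Tex43 at 0.39, Ttll13 at 0.60, Zfp446 at -0.29, Eef1g at -0.34 and the matrix protein Reln at -0.49 (each adjusted p = 0.15). There the fixed term gave 1 call, Ubb-ps at 0.39 (adjusted p = 0.0425). That group holds the array that stands apart, and 4631 and 5019 probes were called without its replicates 1 and 2 and 1 without replicate 1 of the control. At 1 µg/ml limma called 0 probes with the set as a fixed term (431 unadjusted). Abhd16a (4.11 ± 1.25), Ldhc (0.52 ± 0.16) and Spata21 (-0.83) then lay near or above their former size with wider errors, while Mea1 was at -0.52, Ubb-ps at 0.33 and Nop9 at -0.0015. The 46 probes at 1 µg/ml became 579 without the array that stands apart, and 3, 8 and 5 without replicates 1, 2 and 3 of the control. They became 0 without replicate 2 or 3 of 1 µg/ml, 74 and 82 without replicates 2 and 3 of 0.01 µg/ml at 1 month, 132 without replicate 1 of 0.01 µg/ml and 29 without replicate 3 of 1 µg/ml, both at 6 months. Each of the 6 named genes at 1 µg/ml lost its call without at least 1 array. The count at 0.1 µg/ml ran from 0 to 16, moved by 41 of the 46 arrays, and that at 0.01 µg/ml rose to 1 without each of 5 arrays.

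At 12 months Cps1, the first enzyme of the urea cycle, was higher in 1 mouse and Igf2, a growth factor, was lower in another. Their errors and p-values take the spread from other groups, so 1 mouse cannot show an effect of the dose. In the 1 mouse at 1 µg/ml Cps1 was at 9.44 against 7.77 ± 0.03 (SD) in the 2 controls, a rise of 1.67 ± 0.15 (adjusted p = 3.8e-08), Ryr3 rose by 0.45, and Klk1b26, a kallikrein (-2.91 ± 0.49, adjusted p = 0.00686), and Poli, DNA polymerase iota (-1.36 ± 0.25), fell. In the 1 mouse at 10 µg/ml Igf2 was at 9.54 against 11.74 ± 0.26 (SD) in the controls, a fall of -2.20 ± 0.39 (adjusted p = 0.0326), Vamp1 rose by 0.27 and Lgals4 by 0.35. The next smallest p at 10 µg/ml belonged to Fcsk (0.34), Mettl22 (0.67), Lifr (0.32), Pla2g15 (-0.64), Pdlim1 (-0.63), Chst15 (-0.32) and Gnb5 (-0.41), which did not pass. Hsd17b11, a steroid dehydrogenase, fell by 0.83 ± 0.14 at 0.01 µg/ml (2 arrays, adjusted p = 0.0163) and by 0.78 at 0.1 µg/ml (3 arrays, adjusted p = 0.0103). Plscr4 fell by 0.32 ± 0.05 at 0.01 µg/ml, and Cenpx (-0.50) and Khk, the ketohexokinase (-0.43), fell at 0.1 µg/ml. Of these genes only Cps1 and Ryr3 kept their calls without each single array. Without replicate 1 of the control the adjusted p was 0.155 for Hsd17b11 at 0.1 µg/ml, 0.257 for Cenpx, 0.344 for Khk and 0.102 for Vamp1. Without replicate 2 of the control it was 0.426 for Poli, 0.158 for Lgals4, 0.0903 for Igf2 and 0.122 for Klk1b26. At 0.01 µg/ml it was 0.388 for Hsd17b11 and 0.35 for Plscr4 without replicate 2 of that dose, the highest of 4 arrays that each ended the call.

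The lists at 10 µg/ml and 12 months rest on 1 mouse, and their p-values take its genes as evidence, so they cannot show an effect of the dose. There Sertoli (median -0.23) and Leydig cell genes (-0.28) were lower (camera adjusted p = 0.00486 each), as were myoid genes (-0.19, adjusted p = 0.0354), and spermatocyte genes were higher (adjusted p = 0.049). With limma 0 members of these lists passed. With an estimated correlation each call was lost, at adjusted p = 0.350 for the first 3 and adjusted p = 0.173 for spermatocytes. The Sertoli call was lost without replicate 1 of the control (adjusted p = 0.0731), the myoid call without replicate 2 (0.118) and the spermatocyte call without any 1 of 16 arrays, up to 0.0861 without replicate 1 of the control. When the set was a fixed term, Sertoli (adjusted p = 0.000901), myoid and endothelial genes (0.0194 each) were lower and round spermatid genes higher (0.0421), each at adjusted p = 0.429 with an estimated correlation. In all 2 probes rose and 1 fell at 10 µg/ml (1420 unadjusted), 3 rose and 2 fell at 1 µg/ml (845), 6 fell at 0.1 µg/ml (1317) and 2 fell at 0.01 µg/ml (1113). Limma called 0 at 0.001 µg/ml (1139 unadjusted), with Cela1 at 0.79, Rffl at 0.66, Mrpl35 at 0.33, Wfikkn2 at -0.35, Plscr4 at -0.28 and Gnb5 at -0.35. A fixed term for the set put Cps1 at 1 µg/ml at 1.84 ± 0.23, Ryr3 at 0.38 ± 0.11 and Klk1b26 at -3.01. It put Hsd17b11 at 0.01 µg/ml at -0.72 (adjusted p = 0.438) and Igf2 at 10 µg/ml at -2.05 ± 0.63. Only Cps1 kept its call in this fit. That fit called Uvrag at 0.01 µg/ml (-0.41, adjusted p = 0.0158) and Dynlt1b at 1 µg/ml (-0.72, adjusted p = 0.0159), named after their values were seen. Without the array that stands apart it called 49 probes at 0.001 µg/ml. Of the arrays left out in turn, that which stands apart moved the counts most, to 139 at 10 µg/ml, 20 at 1 µg/ml, 97 at 0.1 µg/ml, 52 at 0.01 µg/ml and 23 at 0.001 µg/ml. The count at 10 µg/ml became 11 without replicate 2 of 0.01 µg/ml and 5 without replicate 3 of 1 µg/ml, both at 6 months. That at 0.1 µg/ml became 12 and 10 without replicates 1 and 2 of 0.01 µg/ml at 6 months, 2 without replicate 2 of the control and 0 without replicate 2 of 0.1 µg/ml. Each of the counts at 0.01 and 0.001 µg/ml was moved by 10 arrays, the first to 0 without either of its own replicates.

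**Figure D3:**
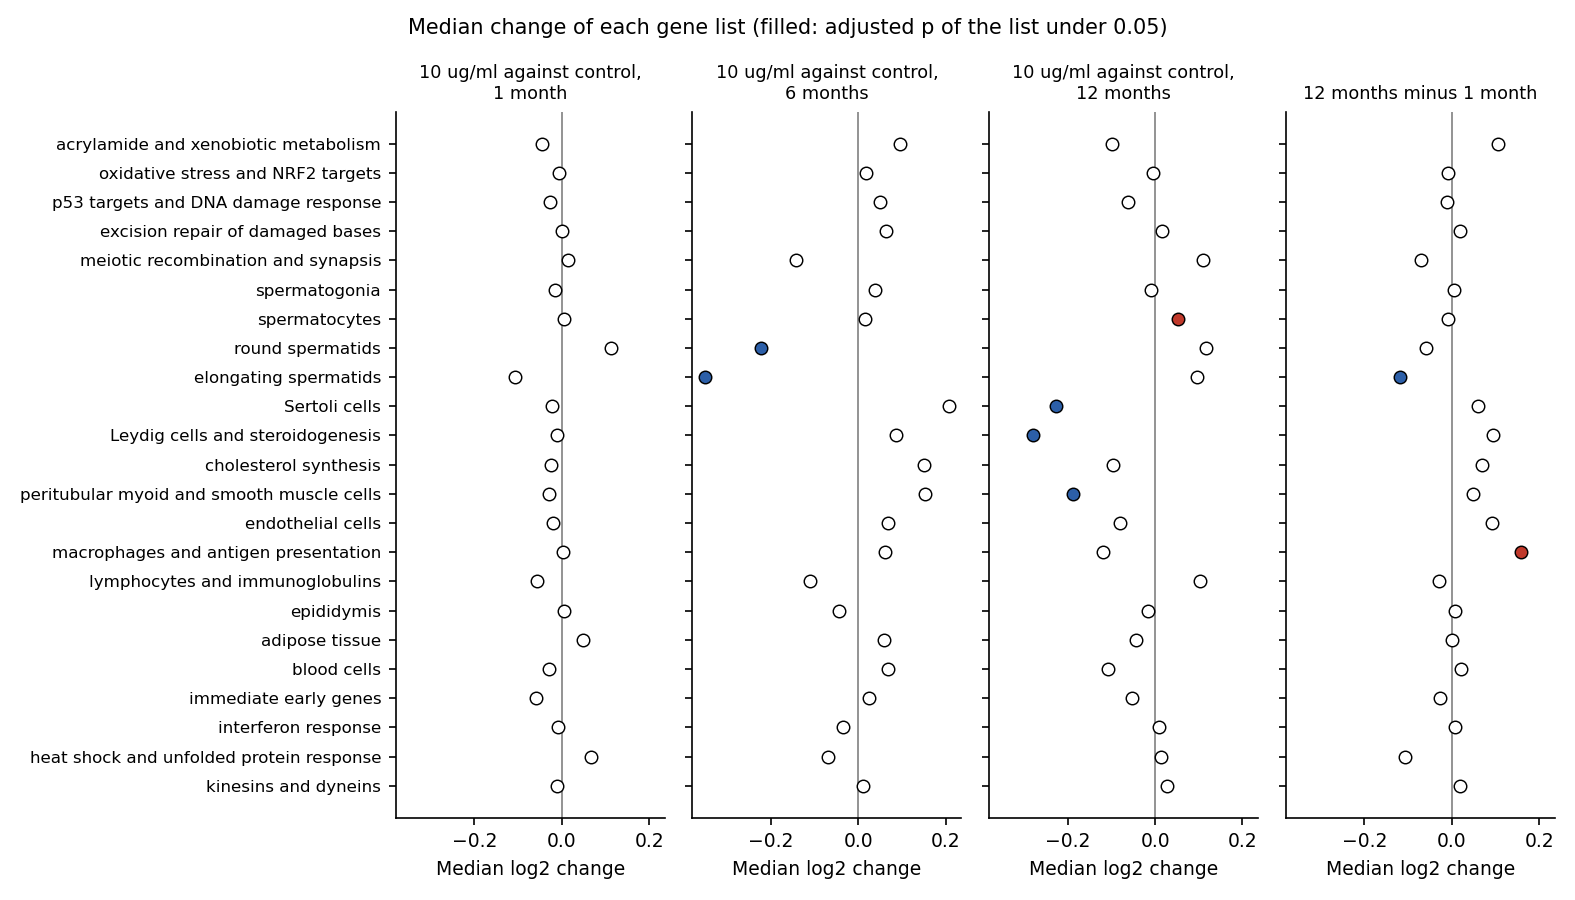
Median log2 change of the members of each gene list for 10 µg/ml against control at 1, 6 and 12 months and for 12 months minus 1 month. A filled point marks a list with an adjusted p under 0.05; the elongating spermatid list stood at -0.35 at 6 months.

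The dose trends asked which genes followed the dose rank at each time. At 6 months (18 arrays), 2135 probes rose and 1952 fell with dose (5785 unadjusted). Falling genes again included those of spermatids, with Odf2 at -0.38 ± 0.05 per dose step (adjusted p = 1.4e-05), Zpbp2 at -0.38 ± 0.06 (adjusted p = 9.7e-05), Ms4a5 at -0.43, Speer6-ps1 at -0.39 and Ropn1 at -0.38. Lower too were Fhl4 at -0.36, Speer1 at -0.35, Bcl2l14 at -0.35, Gkap1 at -0.35, Pde8a at -0.34, Cfap69 at -0.34 and Spata16 at -0.34. Rising genes were Lrrc18 (0.45), Serpinf1 (0.24 ± 0.04, adjusted p = 0.000137), Afap1 (0.19), Rp9 (0.19), Rps2 (0.18), Zyx, a focal adhesion protein (0.17), and Tmem184a (0.17). So were Tubb5, a beta tubulin (0.17 ± 0.02, adjusted p = 3.9e-05), Trpc4ap (0.17), Zfpm1 (0.16), Mfge8 (0.15) and the splicing factor Sf3b2 (0.15). Of 21 elongating spermatid genes 9 fell, with Tnp2 at -0.29, Spz1 at -0.28 and Akap4 at -0.11, and 2 rose, with the protamine Prm1 at 0.13 (median -0.0718, adjusted p = 0.0061, adjusted p = 0.059 with an estimated correlation and 0.145 with cyclic loess, the highest of 12 alternatives, of which the lowest was 5.5e-05). Of 26 Sertoli cell genes 10 rose and 2 fell (list adjusted p = 0.0829), and 8 of 27 heat shock genes fell (0.0764). Other probes of Odf2 (0.04, and 0.08 at adjusted p = 0.0144), Trpc4ap (-0.13, adjusted p = 0.00023), Tmem184a (-0.06) and Rp9 (-0.07) had the opposite sign. Within set 4 the median slope of the elongating spermatid genes was 0.0264, and no fit with the set as a fixed term could be had for this trend. As a random term without the array that stands apart it gave 2527 calls. Without the array that stands apart the count was 6330, and 2 of the 24 genes with the largest slopes lost their call without at least 1 array.

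At 1 month the dose trend (17 arrays) held single genes in both directions and 0 of 23 lists passed. Upward were Abhd16a (0.49 ± 0.12), Ist1 (0.29 ± 0.06, adjusted p = 0.00426), Fcmr (0.24), Oser1 (0.22), and Spata4 (0.21). Further ones were the mitochondrial carrier Slc25a3 (0.21), Gpd2 (0.20), Aqp11 (0.19), Sltm (0.18), Ppp4r1 (0.18), Anxa3 (0.17) and Ddx4, the helicase of germ cells (0.17 ± 0.05). Downward were Pga5 (-0.26), Mea1 (-0.25 ± 0.04, adjusted p = 0.000268), Nop9 (-0.24), Spata21 (-0.23), and Ybx2, a germ cell RNA-binding protein (-0.22). They also took in Klhdc3 (-0.22), Ptpre (-0.22), Gsg1 (-0.21), Tmem53 (-0.21), Wdr31 (-0.20), Akap1, a mitochondrial scaffold (-0.20 ± 0.03, adjusted p = 0.000869), and Cir1 (-0.20). List members that passed were Gpx4 (-0.11), Aptx (-0.13), Ddb1 (-0.11), Polb (-0.10), Hspb1 (-0.12), Hsp90aa1 (0.14), Prm3 (-0.16), Acrv1 (0.08), Catsper3 (0.12), Dnajb3 (0.07) and Id4 (0.15). In all 430 probes rose and 431 fell (3463 unadjusted). Other probes of Ist1 (-0.04), Ddx4 (-0.10), Ybx2 (0.02), Gsg1 (0.03) and Akap1 (0.03, adjusted p = 0.0409) had the opposite sign. With the set as a fixed term limma called 0 probes (776 unadjusted), with Nop9 (0.06), Ybx2 (0.03), Ptpre (0.14) and Akap1 (0.01) above 0. Abhd16a (0.65 ± 0.29), Ist1 (0.36), Fcmr (0.33), Ddx4 (0.32), Gpd2 (0.26), Spata4 (0.24) and Oser1 (0.22) were as high or higher, with wider errors. Within set 2 (8 arrays, 4 doses) limma also called 0 (768). The 861 probes became 393, 450 and 374 without replicates 1, 2 and 3 of the control, 2187 and 2190 without replicates 1 and 2 of 0.001 µg/ml, 486 without replicate 2 of 1 µg/ml and 328 and 319 without replicates 1 and 2 of 10 µg/ml. Of the 24 genes with the largest slopes 13 lost their call without at least 1 array. Pga5 stood at -0.12 (adjusted p = 0.225) without replicate 1 of the control, and Sltm at 0.11 without the array that stands apart. The fixed term for the set put the heat shock list higher (adjusted p = 0.0169, 0.819 with an estimated correlation), and 12 probes were called without that array.

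At 12 months (11 arrays) Cps1 followed dose, at 0.20 ± 0.02 per step (adjusted p = 0.000104), by both of its probes, and these were the 2 probes that passed (1296 unadjusted). Its group means were 7.77 in the control, 7.81, 7.90 and 8.11 ± 0.33 (SD) at 0.001, 0.01 and 0.1 µg/ml, 9.44 at 1 µg/ml and 8.13 at 10 µg/ml, and without the array of 1 µg/ml the slope was 0.08 (adjusted p = 0.289), and without that of 10 µg/ml it was 0.36. Igf2 was at -0.32 ± 0.07 (adjusted p = 0.135), and Rabep1 (0.07), Slc25a25 (0.07), Ash2l (0.05), Fcsk (0.05), Fam117a (-0.10), Pdlim1 (-0.09), Khk (-0.08) and Plcg2 (-0.06) did not pass. With the set as a fixed term limma called 0 probes (339 unadjusted), and within set 6 (6 arrays, 4 doses) it called 0 (287), with Cps1 at 0.23 ± 0.05 (adjusted p = 1). The 2 probes became 17 without the array that stands apart, 4 without replicate 2 of the control, 5 without replicate 1 of 0.001 µg/ml, 0 without the array of 1 µg/ml and 5 without that of 10 µg/ml.

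The trend pooled over the 3 times (46 arrays) had 830 probes rising and 756 falling (3838 unadjusted), of 757 and 679 genes. Spermatid and other genes fell, with Zpbp2 at -0.22 ± 0.04 per step (adjusted p = 0.00111), Spata16 at -0.21, Ptpre at -0.21, Cby2 at -0.20 ± 0.03 (adjusted p = 0.000151) and Odf2 at -0.19. So did the prostaglandin synthase Ptgds at -0.19, Klhdc3 at -0.18, Spata21 at -0.17, Tnp2 at -0.17, Pacrgl at -0.16, Glrx2 at -0.16 and Mea1 at -0.16 ± 0.02. S100a11, a calcium-binding protein (0.12 ± 0.02, adjusted p = 0.000354), Ist1 (0.14), Gtf2ird2 (0.11), Timp2 (0.10), Tmem184a (0.10), Zyx (0.10), and Cldn11 of the Sertoli cell tight junction (0.10) rose. So did Tuft1 (0.10), Serpinf1 (0.09), Afap1 (0.09), Sae1 (0.09) and Galc (0.09). Of 21 elongating spermatid genes 7 fell and 1 rose, with Fscn3 at -0.14 and Oaz3 at -0.10 (adjusted p = 0.00318, adjusted p = 0.0402 with an estimated correlation), and 5 of 26 Sertoli cell genes rose (list adjusted p = 0.36). Other probes of Odf2 (0.02), Ist1 (-0.01 and -0.02), Tmem184a (-0.05) and Ptpre (0.03) had the opposite sign. The count was 3352 without the array that stands apart, 934 without replicate 3 of the control and 922 without replicate 3 of 10 µg/ml, both at 6 months. With dose in µg/ml in place of its rank limma called 0 probes (1235 unadjusted), and no fit with the set as a fixed term could be had; as a random term without the array that stands apart 434 were called.

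**Figure D4:**
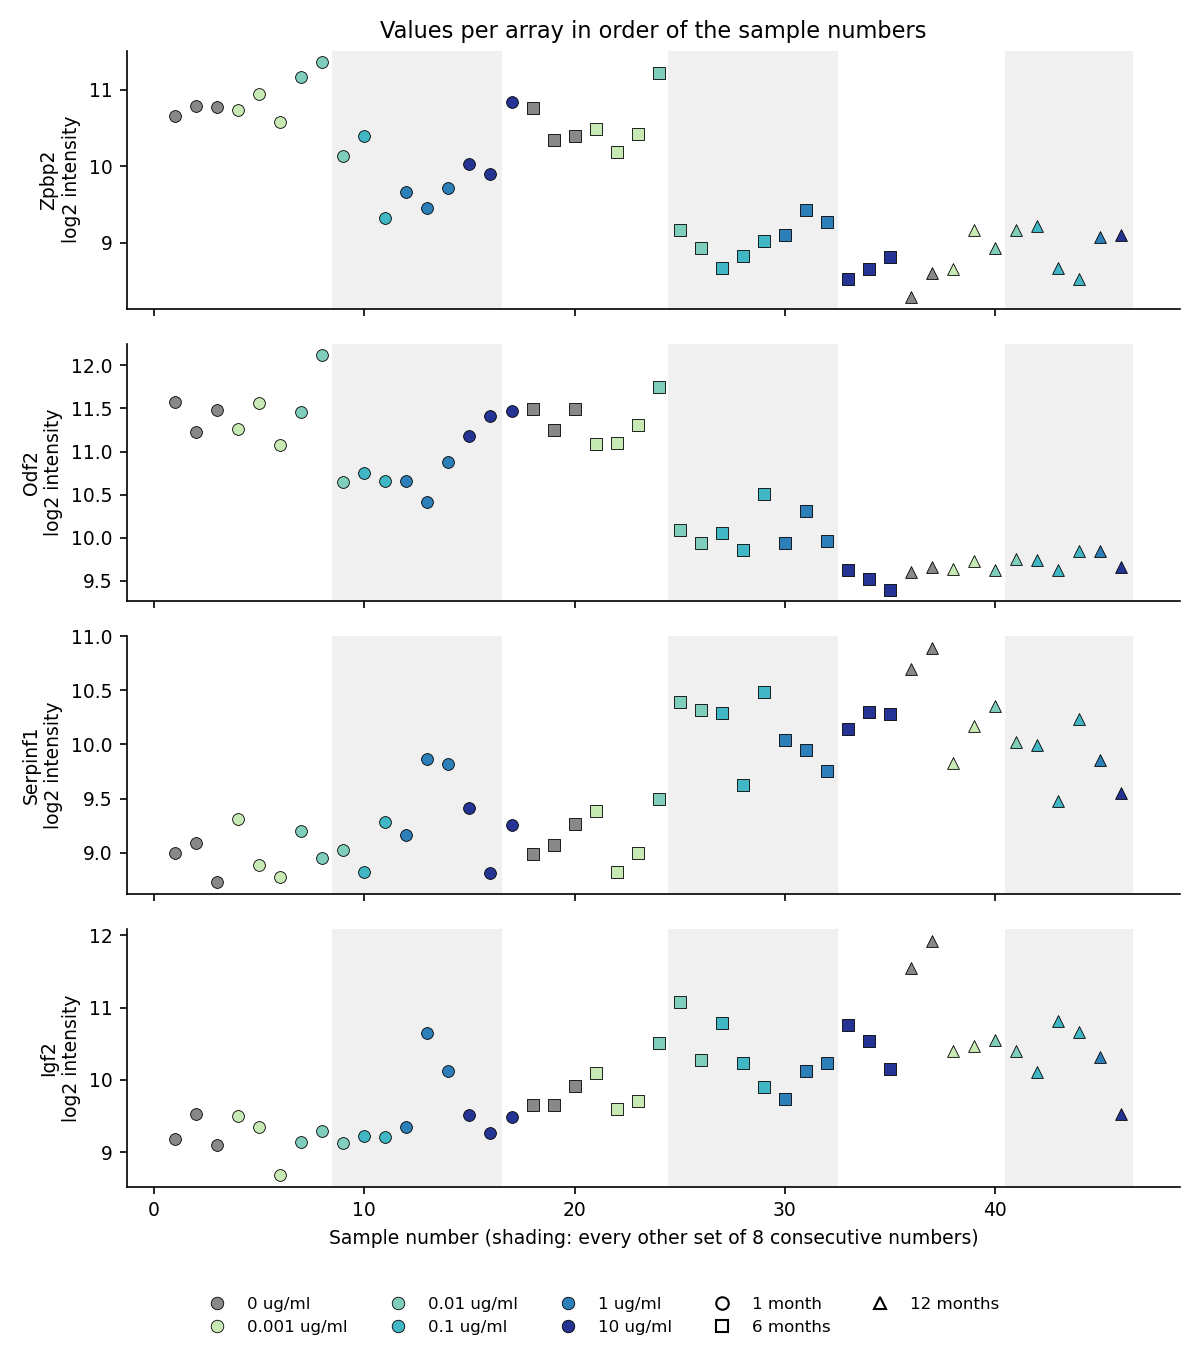
Log2 intensity of Zpbp2, Odf2, Serpinf1 and Igf2 on each array against its sample number, coloured by dose, with a shape for each time and shading over every other set of 8 numbers. The means of Odf2 in sets 1 to 6 were 11.47, 10.83, 11.37, 10.08, 9.60 and 9.75.

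Cyp2e1, the enzyme that converts acrylamide to glycidamide, showed no slope with dose past the threshold at any time. Its 1 probe had a mean of 7.74 and lay between 7.61 and 8.01 on all arrays, and 34.8% of probes were dimmer, so a small change would be hard to see. The slope per dose step was -0.0018 at 1 month (17 arrays), -0.0076 at 6 months (18 arrays) and -0.0114 at 12 months (11 arrays), with two-sided permutation p = 0.868, 0.280 and 0.628 (adjusted 0.868, 0.839 and 0.868). The slope pooled over the times was -0.00623 (limma adjusted p = 0.720).

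**Figure D5:**
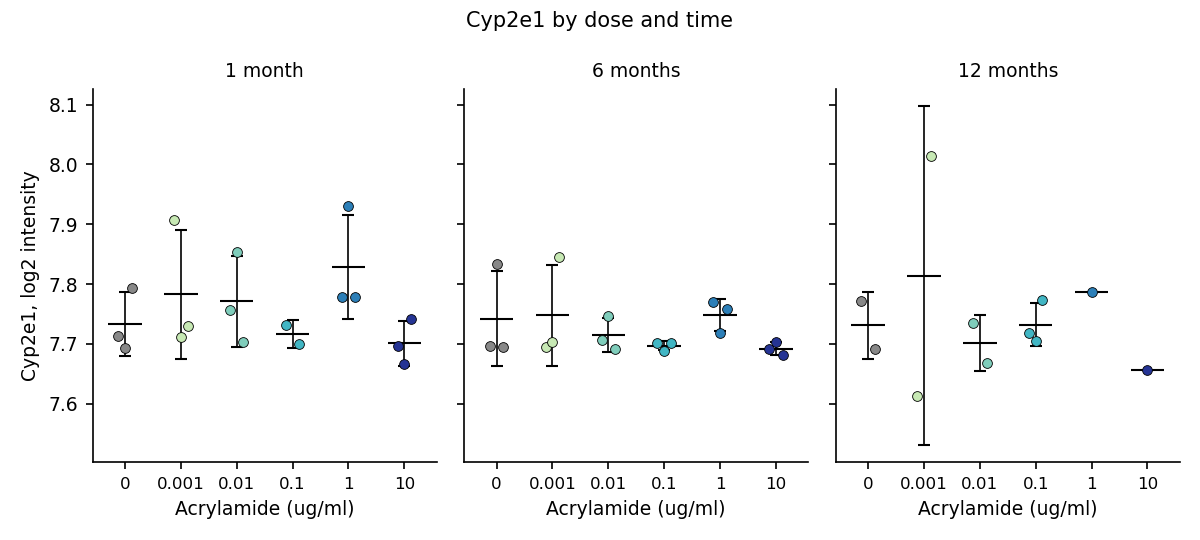
Log2 intensity of Cyp2e1 by acrylamide dose at 1, 6 and 12 months, with a point per array, a line at each group mean and a bar of 1 SD where a group had more than 1 array. All arrays lay between 7.61 and 8.01.

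At 12 months the mice were older than at 1 month (11 against 17 arrays, averaged over doses). Single Leydig cell genes rose, and macrophage genes rose and elongating spermatid genes fell as lists, calls lost with an estimated correlation. Lyz2, a lysozyme of macrophages, rose by 0.87 ± 0.07 (adjusted p = 1.6e-09), Lyz1 by 0.82, C1qc of complement by 0.40 and H2-Ab1, an antigen-presenting molecule, by 0.67 ± 0.18. Of 18 macrophage genes 10 rose and 0 fell (median 0.159, adjusted p = 0.0375, adjusted p = 0.469 with an estimated correlation). Of 26 Leydig cell genes 10 rose, among them Hsd17b3, which makes testosterone (0.79 ± 0.11), Adh1 (0.65) and the hormone Insl3 (0.58), while Hsd3b2 fell (-1.12; list adjusted p = 0.763). Of 21 elongating spermatid genes 8 fell and 5 rose, with Spz1 at -1.17 ± 0.11 (adjusted p = 2.4e-08), Fscn3 at -1.09, Tnp2 at -1.08 and Akap4 at -0.45 (median -0.119, adjusted p = 0.0375, adjusted p = 0.286 with an estimated correlation). Of 13 endothelial genes 7 rose, with Egfl7 at 0.32 (list adjusted p = 0.107), and of 27 heat shock genes 11 fell and 4 rose (0.107). Of 25 xenobiotic genes 11 rose and 4 fell, with Gstk1 at 0.71 and Gstm5 at -0.63. The largest rises were Igf2 (1.12 ± 0.13), the apolipoprotein Apoc1 (1.11), Serpinf1 (0.91), Mfge8 (0.89), Ugt1a10 (0.74) and Ccdc134 (0.65). The largest falls were Ybx3 (-1.47), Zpbp2 (-1.45), Odf2 (-1.43 ± 0.15), Ms4a5 (-1.41), Ptpre (-1.40), Ropn1 (-1.34), Smc5 (-1.28), Cby2 (-1.26), Bcl2l14 (-1.24), Pde8a (-1.20) and Fhl4 (-1.18).

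In all 3525 probes rose and 2821 fell from 1 to 12 months, with a median size of 0.216. Other probes of Lyz2 (-0.12), Lyz1 (-0.04), Hsd17b3 (-0.07), Ybx3 (0.07), Ptpre (0.15) and Odf2 (0.22, and 0.20 at adjusted p = 0.0228) had the opposite sign. From controls alone (2 against 3 arrays) 3074 probes were called, with Igf2 at 2.47, Serpinf1 at 1.86, Lyz2 at 1.09, Odf2 at -1.80 and H2-Ab1 at -0.47, the opposite direction. No set held arrays of 1 and of 12 months, so time and set cannot be told apart in this comparison. The macrophage call was lost in 5 of 11 alternatives (adjusted p = 0.175 from controls alone) and without any 1 of 7 arrays (up to 0.122). The elongating spermatid call was lost in 3 of 11 and without any 1 of 5 arrays (up to 0.0606).

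Between 1 and 6 months (17 and 18 arrays), macrophage genes rose and heat shock genes fell as lists, calls lost with an estimated correlation (adjusted p = 0.329 each). Lyz2 rose by 0.49 ± 0.06 (adjusted p = 1.9e-05), Lyz1 by 0.65, Igf2 by 0.78 ± 0.11, Apoc1 by 0.77, and Serpinf1 by 0.62. Mfge8 rose by 0.59, Hsd17b3 by 0.55, Agt by 0.53, Osr2 by 0.50, C2 by 0.49, Ephx1 by 0.46 and Spink4 by 0.45. Zpbp2 fell by 0.78 ± 0.15, Klhdc3 by 0.72, Ybx3 by 0.70, Spata16 by 0.68 and Odf2 by 0.66. Pacrgl fell by 0.65, Hsd3b2 by 0.62, Ptpre by 0.60, Taf9 by 0.60, Smc5 by 0.58, Morn2 by 0.58 and Tuba8 by 0.57. Of 18 macrophage genes 6 rose (median 0.086, adjusted p = 0.0102), and of 27 heat shock genes 7 fell and 1 rose (median -0.0724, adjusted p = 0.0315). From controls alone the heat shock list was at adjusted p = 0.821, the highest of 11 alternatives, of which the lowest was 0.012. Within set 3, 1 array of 1 month at 10 µg/ml could be set against 7 of 6 months in the control, 0.001 and 0.01 µg/ml, so dose differs as well as time. There Lyz2 differed by 0.47 ± 0.12, Lyz1 by 0.50, Igf2 by 0.39, Zpbp2 by -0.30, Odf2 by -0.12 and Serpinf1 by -0.11, and the macrophage list had a median of 0.0984 with 14 of 18 genes higher. Limma called 0 probes there (648 unadjusted). In all 1446 probes rose and 1219 fell, 4936 passed without the array that stands apart, and from controls alone limma called 0 (359 unadjusted), with Ybx3 (0.08), Hsd3b2 (0.18), Taf9 (0.03) and Morn2 (0.01) in the opposite direction. Other probes of Lyz1 (-0.01), Hsd17b3 (-0.02), Odf2 (0.03 and 0.05) and Ptpre (0.13) had the opposite sign. The heat shock call was lost without replicate 1 (adjusted p = 0.105) or 2 (0.117) of 0.001 µg/ml or replicate 2 of 0.01 µg/ml (0.0517), all at 1 month.

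Between 6 and 12 months (18 and 11 arrays), elongating spermatid genes were lower as a list (lost with an estimated correlation or cyclic loess) and single immune genes rose. H2-Ab1 rose by 0.56, Ly6d by 0.44, Thnsl1 by 0.42, Ncoa4 by 0.42, and Wdr1 by 0.41. Cdk2 rose by 0.41, Yipf7 by 0.41, Retsat by 0.41, Rnf216 by 0.40, Adam4 by 0.38, Lyz2 by 0.38 ± 0.07 (adjusted p = 0.00107) and the chaperone Hspa8 by 0.38. Odf2 fell by 0.77 ± 0.14 (adjusted p = 0.00168), Ptpre by 0.80, Pde8a by 0.80, Ropn1 by 0.80, Ybx3 by 0.77, and Fscn3 by 0.77. Cby2 fell by 0.77, Sppl2c by 0.75, Cdrt4 by 0.75, Bcl2l14 by 0.73, Itgae by 0.71 and Smc5 by 0.70. Of 21 elongating spermatid genes 7 fell and 0 rose (median -0.0884, adjusted p = 0.0314, adjusted p = 0.163 with an estimated correlation, adjusted p from 0.00421 to 0.163 over 11 alternatives), and 3 of 18 macrophage genes rose (list adjusted p = 0.275). Within set 5, the 3 arrays of 6 months were at 10 µg/ml and the 5 of 12 months in the control, 0.001 and 0.01 µg/ml, so dose differs as well as time. There Lyz2 differed by 0.35 ± 0.13, H2-Ab1 by 0.75, Ly6d by 0.70, Fscn3 by -0.13 and Odf2 by 0.14, and the elongating spermatid list had a median of 0.0126. Other probes of Lyz2 (-0.27, adjusted p = 0.0761), Hspa8 (-0.02), Ptpre (0.01), Odf2 (0.16 and 0.25), Ybx3 (0.10) and Sppl2c (0.10) had the opposite sign over all arrays. Limma called 0 rises and 4 falls in set 5 (1056 unadjusted). In all 810 probes rose and 654 fell, and 3730 passed without the array that stands apart, 948 without replicate 1 of 0.01 µg/ml and 3378 without the array of 10 µg/ml, both at 12 months. The elongating spermatid call was lost without replicate 3 of the control (adjusted p = 0.0552), 2 of 0.1 µg/ml (0.0621) or 3 of 1 µg/ml (0.0504) at 6 months or replicate 2 of 0.01 µg/ml at 12 months (0.0521).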

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

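The tests that set arrays of 0.01 µg/ml against each other, the comparison of the array that stands apart with other groups, the counts of list members that it shifted both ways, the correlation of levels over probes of 1 gene and all counts of other groupings were chosen after the result was seen; the other tests were written before the values they measure.

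Dose slopes of genes differed between times by a test of the difference itself. Between 6 and 1 month 658 probes had a higher slope and 1015 a lower one, 1673 in all. Ropn1 of the sperm fibrous sheath (0.10 at 1 month, -0.38 at 6 months, difference -0.48), Mff (-0.51) and Gkap1 (-0.47) had lower slopes at 6 months, and Supt20 (0.25), the chaperone Hspa8 (-0.10 and 0.14, difference 0.24) and Glt8d1 (0.23) higher ones. Between 12 months and 1 month 414 probes differed, with Pga5 (0.65), Mea1 (-0.25 and 0.15, difference 0.40) and Gsg1 (0.35) higher and Cops8 (-0.66), the growth factor Igf2 (0.10 and -0.32, difference -0.42) and Slc25a3 (-0.37) lower. Between 12 and 6 months 2498 differed. The acrosome gene Zpbp2 went from -0.38 at 6 months to 0.10 at 12 months (difference 0.48), with Speer1 (0.56) and Morn2 (0.49) alongside, and Igf2 (-0.44), Serpinf1 (-0.43) and Rp9 (-0.35) were lower at 12 months. Other probes differed in the opposite direction for Hspa8 (-0.03), Glt8d1 (-0.03 and -0.22), Mff (0.07, adjusted p = 0.029), Gsg1 (-0.05) and Rp9 (0.05).

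The count between 6 and 1 month was 2557 and 2749 without replicates 1 and 2 of 0.001 µg/ml at 1 month and 941 without replicate 1 of the control at 6 months. Between 12 months and 1 month it was 1295 without the array that stands apart, 708 and 672 without replicates 1 and 2 of the same group, 272 and 234 without replicates 1 and 3 of the control and 261 without replicate 2 of 1 µg/ml. It was 250 and 246 without replicates 1 and 2 of 10 µg/ml, all at 1 month, and 164 without replicate 1 of the control and 98 without the array of 10 µg/ml at 12 months, where the difference for Igf2 was -0.37 (adjusted p = 0.0562), that for Pga5 0.25 (adjusted p = 0.551), that for Cops8 -0.70 (adjusted p = 0.118) and that for Slc25a3 -0.37 (adjusted p = 0.131). Cops8 lost its call without any 1 of 26 arrays and Slc25a3 without any 1 of 9, the latter up to adjusted p = 0.138 without replicate 1 of the control at 12 months. Between 12 and 6 months it was 4780 without the array that stands apart and 942 without the array of 10 µg/ml at 12 months. With the set as a fixed term limma called 0 probes between 12 months and 1 month, against 414. The named differences became 0.67 ± 0.31 for Pga5, -0.40 ± 0.18 for Igf2, -0.35 ± 0.22 for Slc25a3, 0.24 for Mea1, 0.15 for Gsg1 and -0.37 for Cops8. The first 3 calls thus ended with wider errors at nearly the same size. The term could not be fitted for the other 2 differences.

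At 6 months the spermatid genes Zpbp2 and Ropn1 at 0.1 µg/ml, Odf2 at 1 µg/ml and the elongating spermatid list at 10 µg/ml were lower than in the controls. A fixed term for the set put these 3 genes at 0.51, 0.47 and 0.38, the opposite direction, and no list was tested at 0.1 or 1 µg/ml. A rise of the dose from 0.01 to 1 µg/ml as the source is argued against inside set 4: over the 2679 probes called at 10 µg/ml the difference of 1 from 0.01 µg/ml had a slope of -0.114 on the difference at 10 µg/ml, where that explanation needs more than 0.124, the highest of single arrays within their groups. The set is a candidate explanation for 0.1 µg/ml, since the step between sets 3 and 4 inside the 0.01 µg/ml group followed the difference of 0.1 µg/ml from control with a slope of 0.961 (highest within sets 0.144). It is one for 10 µg/ml too, since the 12-month controls, in set 5, differed from 0.001 µg/ml at 6 months, in set 3, along the difference of 10 µg/ml from control with a slope of 0.922 (highest within sets 0.205), although that contrast holds age as well. The step between sets 3 and 4 inside the 0.01 µg/ml group holds no difference of time or dose. On the same 2679 probes its slope was 0.865, with 97.24% of the signs (highest within sets 0.124). An effect of acrylamide at 10 µg/ml stays open as a biological explanation, because no set holds both 10 µg/ml and a control at 6 months.

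Replicate 3 of 0.001 µg/ml at 1 month differed from the rest of its group by over 1 log2 on 2852 probes, among them Reep6 (4.23), Sox30 (3.74), Cmtm2a (-4.01), Cabyr (-3.63) and Spink2 (-3.60). Noise of single probes is argued against, since its shifts had a correlation of 0.263 over pairs of probes of 1 gene, against 0.145 for 12 months minus 1 month. A label taken from another group is argued against too, as its highest correlation with any array over the 15419 tested probes was 0.818 where the lowest between any other arrays was 0.943. Another share of cell types as the whole source is argued against, because it would move the markers of a type in 1 direction. Of 27 round spermatid genes 5 lay over 1 log2 higher and 6 over 1 log2 lower, and of 21 elongating spermatid genes 3 and 6. Such lists, with at least 3 members each way, numbered 2. Arrays of the other groups of 3 had 0, but with a smaller spread, so that 0 decides nothing. Another share as a part stays open. The medians of 0 of 13 cell type lists lay outside the 95% range of random lists, but these ranges were too wide to decide, as from -1.19 to 0.02 for elongating spermatids. A fault of the array or its labelling, or a testis with a different state, remains open and was not tested.

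Probes of 1 gene often differed in sign: of 3386 pairs with a called probe between 12 months and 1 month, 56.35% had the same sign, as had 57.91% of 1656 pairs at 10 µg/ml and 6 months. Dim probes as the whole source are argued against, because among pairs in the brightest 30% the share was 60.06% of 716. The set is a candidate explanation for a part, since the correlation over probes of 1 gene was lower between neighbouring arrays across a border of sets than within one (0.197 and 0.286, difference -0.0892, exact one-sided permutation p = 0.00057, 4 and 23 pairs, leaving out the pair with the array that stands apart). With that pair the difference was -0.088 (exact one-sided permutation p = 0.000488, 24 pairs within a set). Wrong probe names on every row are argued against, since the mean levels of probes of 1 gene had a correlation of 0.515, where the highest of 200 random pairings was 0.0422. Wrong names on some probes stay open, which bears on the single genes named here. Transcript variants that the probes read separately stay open as a biological explanation and were not tested.

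Other groupings of the arrays gave these counts. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 0 and 4 at 0.001 µg/ml, 0 and 0 at 0.01, 46 and 1 at 1 and 11 and 1 at 10 µg/ml at 1 month. At 6 months they were 0 and 1 at 0.001 µg/ml, 0 and 201 at 0.01, 929 and 0 at 0.1, 48 and 0 at 1 and 2679 and 0 at 10 µg/ml. In the groups with 0 real calls, 10 of the 10 splits gave as many, and in the others 1 did. The split with 201 probes put replicates 1 and 3 of the control with replicate 1 of 0.01 µg/ml, all in set 3, against replicate 2 of the control, in set 3, and the 2 arrays of 0.01 µg/ml in set 4, and so nearly followed the border of the sets. Over 100 groupings that shuffled doses within times, the real count was highest for the trends at 1 month (861, highest other 40, 1 grouping as large). So it was at 6 months (4087 and 1510, 1) and over all times (1586 and 1043, 1), but not at 12 months (2 and 7, 36). Over 100 that shuffled times within doses, it was highest for the trend differences (1673 and 2, 414 and 6, 2498 and 2, 1 each). So it was for 6 (2665 and 1, 1) and 12 months (6346 and 5, 1) against 1 month. It was not for 12 against 6 months (1464, highest other 1759, 2 as large). These groupings mix sets, so they cannot part chance, dose or time from the set.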

How the results depend on the processing

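Restored intensities and all fits with sets of 8 numbers were chosen after the result was seen, as was leaving out the array that stands apart together with a set. Of 476 counts of probes or lists and slopes of Cyp2e1 under the alternatives, 291 stayed within 1.5 times or on their side of the threshold. Of 10435 named-gene values with single arrays left out, 9538 kept their direction and call, 897 no longer passed and 0 reversed, and of 594 list values 40 no longer passed. With the set as a fixed term 63 of 71 named-gene values no longer passed and 7 reversed, and 57 and 10 without the array that stands apart. Among other probes of the genes 72 of 168 did not pass and 58 had the opposite direction, of which 7 passed. From controls alone 26 of 72 no longer passed and 6 reversed. With cyclic loess 56 of 227 named genes and 4 of 13 lists no longer passed, and 0 reversed. The elongating spermatid list was then at adjusted p = 0.0674 for 10 µg/ml at 6 months, 0.145 for the trend at 6 months and 0.104 between 6 and 12 months. The share of called probes that rose at 10 µg/ml and 6 months was 51.8% in the values reported and 35.4% with cyclic loess, while the median of all tested probes was 0.0171 and 0.00912. Cyp2e1 kept a slope below 0 that did not pass, from -0.0249 to -0.0049. Signal over background limits dim probes, whose differences the authors' processing compresses. An alternative with the slide as a block was planned and not run, since no slide is given. The set as a fixed term could not be fitted for 10 µg/ml at 6 months, the trend at 6 months, the pooled trend, the trend differences with 6 months and the time comparisons. The cause of a changed value was not tested, except where an alternative tests other probes or fewer arrays by its construction.

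Counts of probes that moved by more than 1.5 times were as follows, with the count at an unadjusted p under 0.05 in parentheses beside 0, all with limma. Restored intensities with normexp and quantile scaling gave 2 at 0.001, 2 at 0.01, 4 at 1 and 3 at 10 µg/ml at 1 month. They gave 21 at 1 µg/ml at 6 months and 1 at 0.1 and 1 at 10 µg/ml at 12 months. The dose trend had 311 at 1 month and the trend difference between 12 and 1 months 189. Without background correction the restored intensities gave 1 at 0.001, 1 at 0.01, 0 (759 unadjusted) at 0.1, 7 at 1 and 2 at 10 µg/ml at 1 month. Counts at 12 months were 5 at 0.01, 1 at 0.1 and 1 at 10 µg/ml. The dose trend counted 372 at 1 month. Trend differences counted 212 between 12 and 1 months. Cyclic loess on them gave 17 at 0.001, 2 at 0.01, 5 at 0.1 and 6 at 1 µg/ml at 1 month. Counts at 6 months were 390 at 0.1 and 10 at 1 µg/ml. The doses of 12 months counted 0 (776 unadjusted) at 0.01, 0 (862 unadjusted) at 0.1 and 0 (1157 unadjusted) at 10 µg/ml. Dose trends had 0 (957 unadjusted) at 12 months. Differences of trends had 177 between 12 and 1 and 1664 between 12 and 6 months. Lists past the threshold numbered 1 for 10 µg/ml at 6 months, 5 between 6 and 1 months, 4 between 12 and 1 months and 0 between 12 and 6 months. With no filter on dim probes, which tests more probes, counts were 0 (1391 unadjusted) at 0.1, 21 at 1 and 0 (1665 unadjusted) at 10 µg/ml at 1 month. The doses of 6 months counted 31 at 1 µg/ml. At 12 months the counts were 7 at 0.01 and 6 at 10 µg/ml. The lists that passed numbered 4 for 10 µg/ml at 6 months, 4 for the trend at 6 months and 0 between 12 and 1 months. Leaving out the dimmest 60% gave 3 at 0.1 µg/ml at 1 month. Counts at 12 months were 1 at 0.01, 2 at 1 and 1 at 10 µg/ml. For the dose trend they were 0 (876 unadjusted) at 12 months. Lists that passed were 2 between 12 and 6 months. A fit of only the arrays of the times compared, with fewer arrays for the spread, gave 0 (647 unadjusted) at 0.1, 7 at 1 and 0 (799 unadjusted) at 10 µg/ml at 1 month. At 6 months the counts were 1 at 0.01, 1734 at 0.1, 1 at 1 and 4226 at 10 µg/ml. The doses of 12 months counted 5 at 0.001, 15 at 0.01, 18 at 0.1, 0 (1630 unadjusted) at 1 and 47 at 10 µg/ml. The dose trend counted 39 at 1 month and 19 at 12 months. For the trend differences they were 156 between 12 and 1 and 4312 between 12 and 6 months. Time comparisons had 3291 between 12 and 6 months. Lists past the threshold numbered 1 for 10 µg/ml at 6 months and 0 between 12 and 1 months.

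Array weights, whose estimate stopped before its tolerance was reached, gave 7 at 0.001, 11 at 0.01, 514 at 0.1, 1768 at 1 and 1171 at 10 µg/ml at 1 month. Counts at 6 months were 1 at 0.001, 3012 at 0.01, 3772 at 0.1, 2699 at 1 and 5715 at 10 µg/ml. At 12 months the counts were 2 at 0.001, 63 at 0.01, 122 at 0.1, 27 at 1 and 333 at 10 µg/ml. Dose trends had 2637 at 1 month, 6821 at 6 months, 201 at 12 months and 4294 over all times. Trend differences counted 3668 between 6 and 1, 2029 between 12 and 1 and 5163 between 12 and 6 months. Time comparisons counted 6531 between 6 and 1 and 4000 between 12 and 6 months. The lists that passed numbered 1 for the trend at 1 month, 2 for the trend at 6 months and 1 between 12 and 1 months. The robust eBayes with an intensity trend gave 0 (867 unadjusted) at 0.1, 20 at 1 and 0 (1090 unadjusted) at 10 µg/ml at 1 month. The doses of 6 months counted 28 at 1 µg/ml. Differences of trends had 253 between 12 and 1 months. Testing 1 probe per gene gave 26 at 1 and 0 (743 unadjusted) at 10 µg/ml at 1 month. Counts at 12 months were 5 at 0.01, 12 at 0.1 and 1 at 10 µg/ml. For the dose trend they were 1 at 12 months. For the trend differences they were 1082 between 6 and 1 months. Dose in µg/ml in place of its rank gave 6 at 1 month, 1740 at 6 months, 0 (698 unadjusted) at 12 months and 0 (1235 unadjusted) over all times for the dose trend. Trend differences counted 0 (854 unadjusted) between 12 and 1 and 334 between 12 and 6 months. Lists that passed were 4 for the trend at 6 months and 2 for the trend at 12 months. Leaving out 12 months from the pooled trend gave 2945 over all times for the dose trend. Control arrays alone gave 0 (359 unadjusted) between 6 and 1, 3074 between 12 and 1 and 2685 between 12 and 6 months. Lists past the threshold numbered 1 between 12 and 1 months. With an estimated correlation the lists that passed with camera numbered 1 for 10 µg/ml at 6 months and 0 for 10 µg/ml at 12 months, the trend at 6 months and the time comparisons.

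The set of 8 numbers as a fixed term gave 1 at 0.001, 4 at 0.01, 0 (270 unadjusted) at 0.1, 0 (431 unadjusted) at 1 and 0 (840 unadjusted) at 10 µg/ml at 1 month. At 6 months the counts were 1 at 0.001, 0 (284 unadjusted) at 0.1 and 0 (302 unadjusted) at 1 µg/ml. The doses of 12 months counted 1 at 0.01, 0 (412 unadjusted) at 0.1, 3 at 1 and 0 (582 unadjusted) at 10 µg/ml. The dose trend counted 0 (776 unadjusted) at 1 month and 0 (339 unadjusted) at 12 months. Differences of trends had 0 (466 unadjusted) between 12 and 1 months. The lists that passed numbered 2 for 10 µg/ml at 1 month and 1 for the trend at 1 month. The same term without the array that stands apart gave 16 at 0.01, 0 (636 unadjusted) at 0.1, 0 (1028 unadjusted) at 1 and 98 at 10 µg/ml at 1 month. Counts at 6 months were 1 at 0.001, 1 at 0.01, 0 (696 unadjusted) at 0.1 and 0 (752 unadjusted) at 1 µg/ml. At 12 months the counts were 49 at 0.001, 1 at 0.01, 0 (831 unadjusted) at 0.1, 3 at 1 and 0 (1216 unadjusted) at 10 µg/ml. Dose trends had 12 at 1 month and 0 (717 unadjusted) at 12 months. For the trend differences they were 0 (910 unadjusted) between 12 and 1 months. Lists that passed were 2 for 10 µg/ml at 1 month and 1 for the trend at 1 month. The set as a random term without that array gave 1 at 0.01, 0 (753 unadjusted) at 0.1, 3 at 1 and 1 at 10 µg/ml at 1 month. The doses of 6 months counted 1 at 0.001, 0 (2419 unadjusted) at 0.1 and 0 (1463 unadjusted) at 1 µg/ml. Counts at 12 months were 40 at 0.001, 41 at 0.01, 2 at 0.1 and 5 at 10 µg/ml. For the dose trend they were 5 at 1 month, 2527 at 6 months and 434 over all times. Trend differences counted 101 between 6 and 1, 42 between 12 and 1 and 994 between 12 and 6 months. For times the counts were 887 between 6 and 1 months. With all arrays the correlation within sets was estimated at -0.00238, so the random term could move nothing and says nothing about the set; without the array that stands apart it was 0.172.

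With the replicate block within each time, for numbers that do not pair the arrays, counts were 21 at 1 µg/ml and 1 month, 10 at 1 µg/ml and 6 months, 4 at 0.01 µg/ml and 0 (1291 unadjusted) at 10 µg/ml and 12 months, and 213 for the trend difference between 12 months and 1 month. The replicate block could not be fitted for the time comparisons.

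Leaving out each of the 46 arrays in turn, limma gave 0 to 5019 at 0.001, 0 to 1 at 0.01, 0 to 16 at 0.1, 0 to 579 at 1 and 0 to 142 at 10 µg/ml at 1 month. At 6 months the ranges were 0 to 1 at 0.001, 0 to 858 at 0.01, 192 to 2852 at 0.1, 0 to 1361 at 1 and 1242 to 5073 at 10 µg/ml, and at 12 months 0 to 23 at 0.001, 0 to 52 at 0.01, 0 to 97 at 0.1, 4 to 20 at 1 and 2 to 139 at 10 µg/ml. For the dose trend they were 319 to 2190 at 1 month, 2979 to 6330 at 6 months, 0 to 17 at 12 months and 922 to 3352 over all times. For trend differences they were 941 to 2749 between 6 and 1, 98 to 1295 between 12 and 1 and 942 to 4780 between 12 and 6 months, and between times 1858 to 4936 between 6 and 1, 5839 to 8517 between 12 and 1 and 948 to 3730 between 12 and 6 months. The number of lists that passed ran from 1 to 3 for 10 µg/ml at 6 months, 2 to 6 for 10 µg/ml at 12 months, 1 to 4 for the trend at 6 months, 0 to 1 for the trend at 12 months, 1 to 6 for 6 and 1 months, 0 to 2 for 12 and 1 months and 0 to 1 for 12 and 6 months.

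With control arrays alone the direction turned, by log2 value, to Ybx3 0.078, Hsd3b2 0.18, Taf9 0.034 and Morn2 0.0094 for 6 and 1 months, and H2-Ab1 -0.47 for 12 and 1 months. It turned to Yipf7 -0.044 for 12 and 6 months. With the set as a fixed term it became Zpbp2 0.51 and Ropn1 0.47 for 0.1 µg/ml at 6 months, and Odf2 0.38 for 1 µg/ml at 6 months. That term also gave Nop9 0.056, Ybx2 0.033, Ptpre 0.14 and Akap1 0.0068 for the trend at 1 month. Without the array that stands apart the same term gave the same values for Zpbp2, Ropn1 and Odf2. It also gave Nop9 0.070, Ybx2 0.088, Klhdc3 0.033, Ptpre 0.12, Gsg1 0.012, Tmem53 0.011 and Akap1 0.0078 for the trend at 1 month. Other probes of a gene that had the opposite direction stood at Ruvbl1 (0.083 and 0.13) for 10 µg/ml at 1 month. At 6 months they were Odf2 (0.23 and 0.29) for 1 µg/ml and Trpc4ap -0.60, Mff 0.36 and Odf2 (0.19 and 0.36) for 10 µg/ml. At 12 months they were Hsd17b11 0.0029 for 0.1 µg/ml and Lgals4 -0.048 for 10 µg/ml. Others stood at Ist1 -0.038, Aqp11 -0.0088, Ddx4 -0.097, Ybx2 0.016, Ptpre 0.043, Gsg1 0.035, Wdr31 0.067, Akap1 (0.030, 0.029 and 0.040) and Cir1 0.047 for the trend at 1 month. There were also Rp9 -0.067, Tmem184a -0.056, Trpc4ap -0.13 and Odf2 (0.043 and 0.077) for the trend at 6 months. For the pooled trend there were Ist1 (-0.025 and -0.012), Tmem184a -0.051, Tuft1 -0.0066, Sae1 -0.0036, Ptpre 0.034 and Odf2 0.024. For the trend differences they were Hspa8 -0.025, Glt8d1 (-0.026 and -0.22) and Mff 0.066 between 6 and 1 months. Gsg1 was at -0.046 between 12 and 1 and Rp9 at 0.053 between 12 and 6 months. Values of the other sign were Lyz1 -0.0089, Hsd17b3 -0.018, Odf2 (0.034 and 0.052) and Ptpre 0.13 for 6 and 1 months. Others stood at Lyz2 -0.12, Lyz1 -0.040, Hsd17b3 -0.072, Ybx3 0.071, Odf2 (0.22 and 0.20) and Ptpre 0.15 for 12 and 1 months. There were also Lyz2 -0.27, Hspa8 -0.025, Ptpre 0.012, Odf2 (0.25 and 0.16), Ybx3 0.098 and Sppl2c 0.10 for 12 and 6 months.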

Other observations

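All values within or between sets were computed after the result was seen, and the group means at 12 months belong to the planned fit.

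Between sets 3 and 4 inside 0.01 µg/ml at 6 months, the median of the elongating spermatid list was -0.204, beside -0.352 for 10 µg/ml against control, that of round spermatids -0.015 beside -0.223, that of Sertoli cells 0.040 beside 0.208 and that of Leydig cells 0.15 beside 0.086.

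At 12 months Igf2 was at 11.74 ± 0.26 (SD) in the 2 controls and at 10.44 and 10.47 in the groups of 0.001 and 0.01 µg/ml, 10.53 ± 0.37 (SD, n = 3) at 0.1 µg/ml, 10.32 at 1 µg/ml and 9.54 at 10 µg/ml.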
